A study of Canis lupus familiaris with 36 samples.

How the data were processed

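Total RNA came from lymph node aspirates of 6 dogs with B-cell lymphoma that had been kept in RNAlater, per the labels' protocols, with column purification including DNase treatment and RNA integrity numbers above 9.0. Per the labels' protocols, the RNA was amplified and labelled with Cy3 with a low-input one-colour kit. Which drugs were given is not stated in the sources used here. Each dog and phase has 3 arrays under 1 source name, so the dog was taken as the replicate across dogs.

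The deposited scanner files hold spot intensity on a linear scale, extracted with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. Per the file headers each of the 36 arrays has 45220 spots, of which 1417 are controls, and 43603 probes, 50 of them on more than 1 spot. The values used were the processed signal, the scanner software's own background-corrected intensity. The deposited series table of intensity values equals the scanner's median signal exactly in all 45220 rows of each of the 36 columns, so it is linear, not background-subtracted, and neither scaled nor centred, and it was used only as an alternative. Its column medians for arrays 1, 2 and 3 were 174.25, 163.5 and 145.5 in the sensitive and 199, 180 and 188.75 in the resistant phase of Dog 5, and 198, 203 and 195 against 187, 193 and 191.5 in Dog 6. They were 172, 173.5 and 177 against 156.5, 149.75 and 151 in Dog 7, and 213, 207 and 201 against 193, 209 and 213 in Dog 8. In Dog 9 they were 133, 124 and 123 against 112, 119 and 123.5, and in Dog 10 they were 114.75, 117 and 100 against 95.5, 94 and 95.

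The log2 processed signal minus the array's 75th percentile was the unit of all levels. That percentile ran from 626.6 to 1868.8 on the linear scale and was lowest in Dog 10, where the fewest genes were well above background. Whether dim genes were measured less precisely there was not tested, and the number of arrays limits the precision everywhere. Control spots and spots marked as outliers by the scanner software were left out, no spot was saturated, and spots of a probe were averaged. On 3 arrays 365, 442 and 455 spots were marked as outliers, against 43 or fewer on the others. Kept were genes whose probe was well above background on at least 2 of 3 arrays in at least 3 of the 12 dog-and-phase samples. A probe not well above background on any array of a phase has only a bound there. Its change is given as "at least N-fold", the mean of the brighter phase against, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

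Probes were named through the unversioned accession in the files and a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, used for names only, with no coordinates. Of 43603 probes, 1302 had 1 symbol (826 distinct symbols), 0 had several, 11 had only a placeholder name, and all others stayed unnamed here. For a symbol with several probes the one with the highest mean signal was used.

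Tests were run with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading. Across dogs, the 3 arrays were averaged and the 12 means were fitted with the dog as a block, since the labels name the dog of every array. Within dogs, all 36 arrays were fitted with 1 mean per dog and phase, which share the estimate of array spread, and a gene was called at an adjusted p (Benjamini-Hochberg) under 0.05 and an absolute log2 change of 1 or more. An F-test of the 6 changes gave the genes whose change differs between dogs. Of 35 gene lists, 13 had at least 5 kept members and were tested with camera at a preset correlation of 0.01, adjusted over 13 lists across dogs and over 78 list-and-dog pairs within dogs. The other 22 lists were not tested as lists. Only part of each tested list was measured, for example 5 of 55 DNA repair genes, 6 of 46 glutathione and drug detoxification genes, 8 of 50 interferon genes and 5 of 30 T cell genes. A list result therefore covers its measured members and not the whole pathway. Among untested lists, 2 of 31 p53 pathway genes and 0 of 29 glucocorticoid response genes were kept. Exact sign flips over the 6 dogs were two-sided unless stated.

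The groups, tests, lists, main settings and most alternatives were fixed before the data were examined, as was the rule for named genes. That rule took, across dogs, up to 12 named genes per direction that passed with one sign in all 6 dogs, filled by one-sign genes with a mean of 1 or more and the smallest p. It took the 4 highest and 4 lowest named genes with an adjusted p under 0.05 in each dog, 4 members of each list called across dogs, and 2 members of each list called in a dog. It also took 15 genes of interest, of which ABCB1, ABCC1, MYC, BCL2 and MS4A1 were kept. ABCC5, EDN3, F8, PTGS1, CCL5 and KLRD1, and other genes that the rule did not take in the dog in question, were chosen after their values were seen. Some genes that the rule took are not reported here.

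Arrays lay on 10 slides scanned on 4 days, and each dog had both phases on 1 day and 1 slide with both phases. That slide held 1 array of one phase and 3 of the other in every dog, so values within slides rest on a single array of one phase, assumed to vary like the others. Slide was fitted as a block, and changes were also taken within the slides that held both phases. Other alternatives were quantile normalisation, the series table, no filter or a filter on all 36 arrays, every probe kept, leaving out each dog or each array number, an intensity trend with robust estimation, a random block, a fit of 1 dog's arrays alone, no minimum fold, fry, and an estimated correlation. The normexp correction with an offset of 50 was to use the mean signal. It was run on the median signal and background median of all spots instead, because the files used here have no mean signal column. This change, the series table scaled to the 75th percentile, the fit without the 3 arrays rich in outlier spots, the changes within slides, slide as a block for lists and named genes, the filter within a dog, and sign flips for lists were chosen after seeing the data.

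The fits were tested on simulated data built from 32912 genes. For changes of 1, 2 and 4 on the log2 scale, 32.8, 77.6 and 98.5 percent were recovered across 6 dogs with 6 false calls. In Dog 5, 32.8, 95.5 and 98.5 percent were recovered with 5 false calls, and differences between dogs were found for 50.7, 88.1 and 98.5 percent with 9 false calls. A simulated slide effect alone, drawn for each gene with an SD of 0.5 on the log2 scale, gave 5172 false calls without a block. It gave 0 with slide as a block or within slides. The size of that effect was set and not estimated from the arrays, so 5172 says nothing about the real counts.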

Results

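Gene expression was measured in lymph node cells of 6 dogs with B-cell lymphoma, named Dog 5 to Dog 10, each sampled by needle aspirate at a phase when the tumour was sensitive to drugs and at a phase when it was resistant. Every dog and phase was hybridised to 3 one-colour Agilent arrays, 36 arrays in all. The study asked which genes changed between the 2 phases of each dog. The 2 samples of a dog were also taken at different times, so phase, time and any treatment in between cannot be told apart. Below, "in resistance" means in the sample of the resistant phase. Of 43603 probes per array, 25041 to 34432 (57.4 to 79.0 percent) were well above background, with the lowest number in Dog 10, and 32912 genes were kept. A gene here is a named gene or a probe without a name, and 688 of those kept had a name. Correlations of log2 signal had a median of 0.991 between arrays of the same dog and phase, 0.980 between the phases of a dog and 0.961 between dogs. Most pairs of dogs also differed in scan day. All log2 changes are resistant minus sensitive. The dog was the replicate across dogs (n = 6). Within a dog the error is the standard error (SE) of the difference between means of 3 arrays per phase. It uses 1 array spread per gene, pooled over all 36 arrays, so it is not the spread of that dog's own arrays. The p-values within a dog cover array spread only, because the 3 arrays may be technical repeats of one RNA.

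The first comparison asked for changes shared by the 6 dogs. CCR3, the eotaxin receptor of eosinophils, had the highest mean log2 change of the named genes with one direction in every dog, 2.69 (SE 0.69, n = 6 dogs), from a level of -3.01 ± 1.70 (SD) in the sensitive phase to -0.32 ± 2.47 in the resistant phase. GNB3, a beta subunit of heterotrimeric G proteins, had a mean change of 1.43 (SE 0.27), from 0.17 ± 2.13 to 1.59 ± 1.87. The lens protein gene LGSN had a mean change of 1.42 (SE 0.46), was well above background in 3 of the 12 samples, and lay at 0.31 on a dimmer second probe, at 0.91 without Dog 5 and at 0.38 with normexp. The second GNB3 probe gave 0.61. None of these passed the test, with adjusted p = 0.942 for each in paired limma, and their exact sign-flip p of 0.0313, the smallest that 6 dogs can give, was fixed by choosing genes with one direction.

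No gene of the 32912 passed paired limma on the 12 dog-and-phase means at an adjusted p under 0.05, and the smallest adjusted p was 0.942. At an unadjusted p under 0.05 there were 1364 genes (626 higher and 738 lower in resistance), against 1646 expected with no effect. Without the dog as a block limma called 0 genes (178 unadjusted), with an intensity trend and robust estimation 0 (1269), with slide as a block 0 (1363) and within slides 0 (1343). A fit of all 36 arrays with the dog and phase sample as a random block called 631 genes, 337 higher and 294 lower, at a consensus correlation of 0.849 (3911 unadjusted). That fit uses 1 correlation for every gene and counts arrays rather than dogs, so it can understate the spread between dogs. The direction was shared by all 6 dogs for 769 genes, of which 402 were higher, against 1028 expected if directions were independent (exact one-sided p = 0.656 over 32 sign patterns). No gene changed at least 2-fold one way in all 6 dogs (1 without array 2 of each group), and 7 did so in at least 5.

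Genes tied to drug resistance were followed in every dog. ABCB1, which encodes the efflux pump P-glycoprotein, had a mean log2 change of 1.41 (SE 0.55, 2.66-fold, n = 6 dogs) and was higher in 4 of 6 dogs, but did not pass (adjusted p = 0.942 by limma, exact sign-flip p = 0.156). Without Dog 5 the mean was 0.91. By dog, ABCB1 rose by 3.94 in Dog 5 (SE 0.052), by 2.32 in Dog 6 (4.99-fold) and by 2.22 in Dog 8 (4.66-fold), and within the slide that held both phases, where one phase had 1 array, these changes were 3.96, 2.35 and 2.30. In Dogs 7, 9 and 10 ABCB1 was at -0.32, 0.81 and -0.50, and its second probe at -1.11, 0.91 and 0.09. The other efflux transporters had mean changes of 0.30 (SE 0.20) for ABCC1 and -0.62 (SE 0.27) for ABCC5. The oncogene MYC was at -0.29 (SE 0.20), the survival gene BCL2 at 0.06 (SE 0.27), and MS4A1, the gene of the B-cell antigen CD20, at -0.22 (SE 0.18). None of these 5 genes passed, and the sign of the BCL2 mean turned when Dog 6, 8 or 10 was left out and in the deposited table. The mean of MYC was -0.13 without Dog 9, that of MS4A1 -0.05 without Dog 5, and that of ABCC1 0.18 without Dog 6 and 0.16 in the deposited table.

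**Figure D1:**
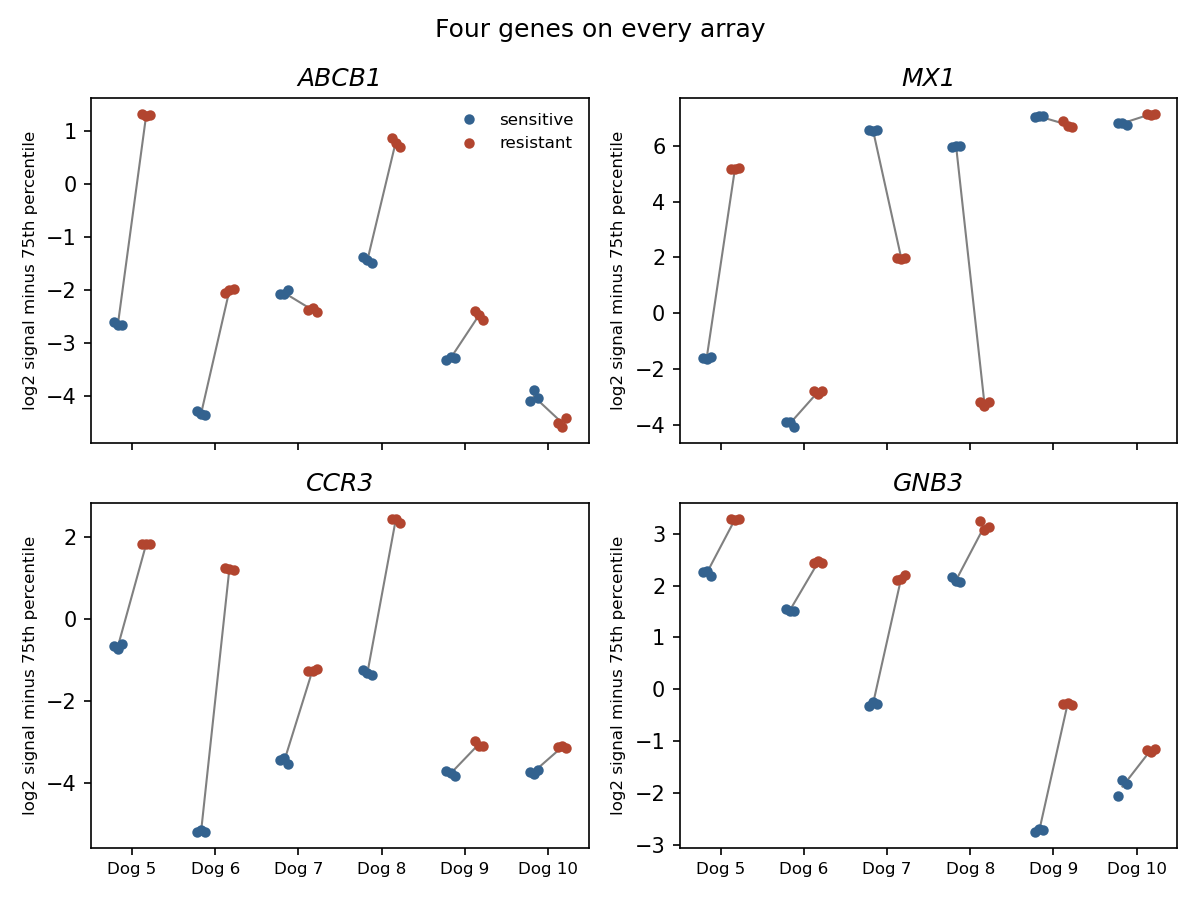
Log2 signal minus the array's 75th percentile of ABCB1, MX1, CCR3 and GNB3 on every array, by dog, with sensitive arrays in blue, resistant arrays in red and lines joining the phase means. ABCB1 is higher in resistance by 3.94 in Dog 5, 2.32 in Dog 6 and 2.22 in Dog 8, while MX1 moves from -1.61 to 5.18 in Dog 5 and from 5.98 to -3.24 in Dog 8.

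Genes of MHC class II and antigen presentation, which display peptides to helper T cells, had a mean change below 0, largely through Dogs 5 and 7. The 7 measured members had a mean log2 change of -0.58 (SD 0.72 over dogs), below 0 in 5 of 6 dogs. By dog the list mean was -1.47, -0.05, -1.53, -0.22, 0.06 and -0.29 in Dogs 5 to 10 in order. DLA-DMA, which loads peptides, was at -0.74 (SE 0.30), DLA-DQB1 at -0.60 (SE 0.25), DLA-DOB at -0.91 (SE 0.41) and DLA-DRA at -0.71 (SE 0.33). The list was shifted down against other genes in camera with a preset correlation (adjusted p = 0.000539). That call was lost at adjusted p = 0.745 with an estimated correlation. Against no change, rather than against other genes, the list did not pass, with adjusted p = 0.516 in fry and 0.609 in exact sign flips. Of the members, 0 passed over all genes, 0 passed adjusted over the list alone, and 2 had an unadjusted p under 0.05. Without Dog 5 DLA-DMA was at -0.47 and DLA-DRA at -0.36, and without Dog 7 DLA-DOB was at -0.45.

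The other 12 gene lists did not pass across the 6 dogs at the main settings, although 4 of them did under alternatives, most of which were planned. DNA repair genes had a mean change of 0.22, above 0 in 5 of 6 dogs, and MHC class I genes -0.23, both at adjusted p = 0.0704 in camera. Stroma and endothelium genes lay at -0.20 (adjusted p = 0.165), NF-kB pathway genes at -0.15 (0.264), glutathione and drug detoxification genes at -0.15 (0.547), neutrophil genes at -0.36 (0.547), interferon response genes at -0.25 (0.660) and T cell genes at 0.09 (0.678). Anti-apoptotic genes lay at 0.02 (adjusted p = 0.759), pro-apoptotic genes at -0.02 (0.905), macrophage and dendritic cell genes at -0.04 (0.905) and receptor tyrosine kinase, PI3K and RAS genes at -0.11 (0.905). For the pro-apoptotic and macrophage lists camera's direction was up although their means were below 0. In each of these lists 0 members passed over all genes and 0 adjusted over the list alone. The interferon list had the widest spread between dogs of the 13 lists (SD 2.13).

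Of the alternatives named next, normexp, the scaled table and the fit without 3 arrays were chosen after seeing the data, and the others were planned. In camera with the preset correlation, MHC class I genes were lower and passed with normexp (adjusted p = 0.000278), in the deposited table (0.00695, and 0.000506 when scaled), without a filter (0.0338) and with the filter on all arrays (0.0209). They also passed without the 3 arrays rich in outlier spots (adjusted p = 0.0382), without Dog 5 (0.0104), without Dog 10 (0.0247) and without array 1 (0.0455). With all dogs at the main settings, the estimated correlation of this list was 0.528, and camera with it gave adjusted p = 0.800. The alternatives named here were not rerun with an estimated correlation. Without Dog 5 interferon genes had a mean of -0.80 and passed (adjusted p = 0.0183), as did NF-kB genes (-0.27) and stroma and endothelium genes (-0.29), both at adjusted p = 0.0470. With all dogs the estimated correlations of the interferon, NF-kB and stroma lists were 0.786, 0.145 and 0.332, against the preset 0.01. Camera with these gave adjusted p = 0.938, 0.800 and 0.800. Stroma and endothelium genes also passed without Dog 9 (-0.45, adjusted p = 0.0332), while their mean was 0.03 without Dog 7. The interferon mean turned to 0.08 without Dog 7 and to 0.41 without Dog 8. Single dogs moved other means by over 1.5 times. NF-kB genes lay at 0.00 without Dog 8, -0.03 without Dog 7, -0.10 without Dog 10, -0.23 without Dog 6 and -0.27 without Dog 9, neutrophil genes at -0.16 without Dog 10, -0.20 without Dog 8 and -0.65 without Dog 9, and glutathione and drug detoxification genes at -0.08 without Dog 10. Without Dog 8 MHC class I genes lay at -0.12, receptor tyrosine kinase genes at -0.06, stroma genes at -0.01 and T cell genes at 0.32, and without Dog 7 T cell genes lay at 0.31. Receptor tyrosine kinase genes lay at -0.17 without Dog 9, and interferon genes at -0.48 without Dog 6 and -0.38 without Dog 10. The means of the T cell, macrophage, receptor tyrosine kinase and both apoptosis lists, all near 0, turned sign under at least 1 alternative each.

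The second comparison took each dog alone, with genes called at an adjusted p under 0.05 in limma and a change of at least 2-fold. Dog 5 had 3805 changed genes (1762 higher, 2043 lower), Dog 6 had 1842 (1079 and 763), Dog 7 had 3607 (1202 and 2405), Dog 8 had 2662 (601 and 2061), Dog 9 had 3785 (2887 and 898) and Dog 10 had 2491 (235 and 2256), or 5.6 to 11.6 percent of genes. With slide as a block the counts were 3193, 1744, 3453, 3065, 4232 and 942, and within the slide that held both phases 3158, 1722, 3428, 3045, 4197 and 938. The count of Dog 10 therefore depended on the slide or on a single array. Its slide with both phases held only array 3 of the sensitive phase, so slide and array cannot be told apart. The count of Dog 10 was 1420, 1330 and 4166 without array 1, 2 or 3 of each group. Some calls were of genes dim in both phases of the dog. Among genes well above background on at least 2 of 3 arrays in either phase of that dog, fewer were called. The counts were then 3715, 1821, 3551, 2422, 3292 and 1776 in Dogs 5 to 10 in order. Scaling moved the split of higher against lower calls. Quantile normalisation gave 1995 higher and 1431 lower in Dog 9 and 639 and 1406 in Dog 10, and the deposited table without scaling gave 2648 and 441 in Dog 5, 313 and 903 in Dog 6, 383 and 1622 in Dog 7 and 338 and 2432 in Dog 9. In that unscaled table the median of all genes moved to 0.27 in Dog 5 and -0.23 in Dog 9, against -0.10 and 0.07 in the scaled values. The split also moved when slide was a block, where slide and a single array cannot be told apart, and without a minimum fold. With slide as a block there were 2741 higher and 1491 lower in Dog 9 and 297 and 645 in Dog 10, and a fit of the arrays of Dog 10 alone gave 154 and 636. With no minimum fold the splits were near even, 8651 higher and 10089 lower in Dog 5, 7387 and 8880 in Dog 6, 9448 and 9039 in Dog 7, 7184 and 7382 in Dog 8, 10103 and 9491 in Dog 9 and 8856 and 8462 in Dog 10.

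**Figure D2:**
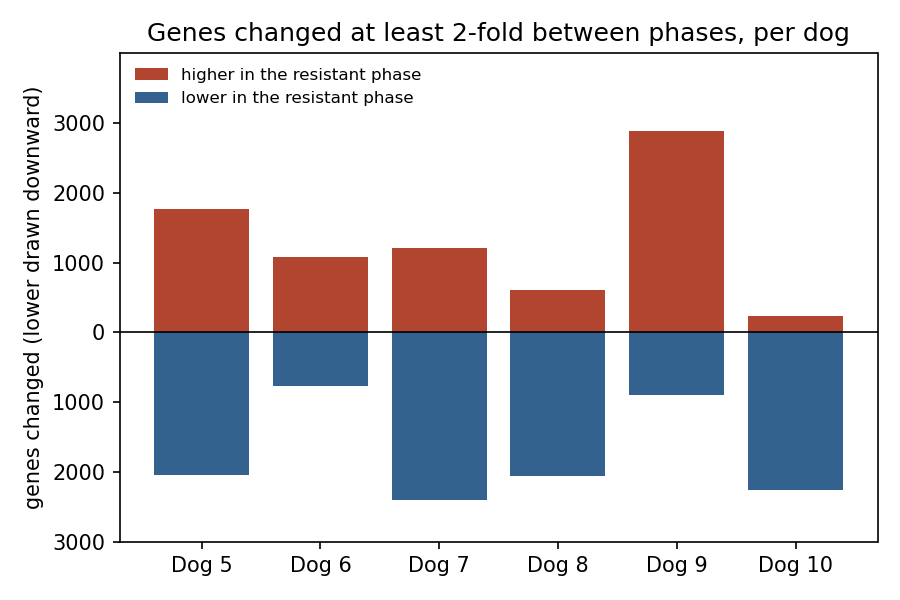
Number of genes changed at least 2-fold between phases in each dog, with bars above 0 for genes higher in resistance and bars below 0 for genes lower in resistance. Dog 9 has 2887 higher and 898 lower genes, and Dog 10 has 235 higher and 2256 lower, while with no minimum fold the splits are 10103 and 9491 in Dog 9 and 8856 and 8462 in Dog 10.

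In Dog 5, interferon response genes rose together. MX1, an interferon-induced antiviral GTPase, rose by 6.79 (SE 0.049, 111-fold) and CXCL10, an interferon-induced chemokine, by 5.14 (SE 0.046, 35.3-fold). The Wnt receptor gene FZD6 rose by 6.41 (SE 0.17), with 1 of 3 sensitive arrays well above background, and the sodium channel gene SCN10A by 4.60. RHPN2 (-3.16), the substance P receptor gene TACR1 (-2.92), the IgE receptor gene FCER1A (-2.73) and the interleukin-2 receptor gene IL2RA (-2.54, 5.80-fold lower, SE 0.091) fell. Of the 8 interferon genes 5 rose, with a list mean of 2.52 (camera adjusted p = 1.3e-06, adjusted p = 0.00454 with an estimated correlation). Of the 7 MHC class II genes 6 fell, among them DLA-DRA (-2.46) and DLA-DMA (-2.08), with a list mean of -1.47 (adjusted p = 0.000193, adjusted p = 0.00454 with an estimated correlation). Macrophage and dendritic cell genes rose with a list mean of 0.48, 1 of 7 members at least 2-fold (CD163, a scavenger receptor, 1.09; FLT3 0.99), at adjusted p = 0.0342 that became adjusted p = 0.064 with an estimated correlation. In the same dog MS4A1 lay at -1.06, and the cytotoxic cell genes CCL5 and KLRD1 lay at 4.06 and 2.46. FZD6 ranged from 3.85 to 7.18 over the alternatives, a dim second FCER1A probe at -0.77 did not pass, and the second CD163 probe at 0.75 was under 2-fold. CD163 was also under 2-fold with normexp (0.90), where FLT3 was at 0.50, SCN10A at 3.04 and FCER1A at -1.40, and in the deposited table RHPN2 was at -1.68, TACR1 at -1.79 and FCER1A at -1.01. The macrophage call ended with normexp (mean 0.29), in the deposited table (0.75, and 0.32 when scaled), with the filter on all arrays and without array 3.

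In Dog 6, CCR3 rose by 6.40 (SE 0.041, 84.4-fold), the endothelin gene EDN3 by 2.81 and the keratin gene KRT12 by 2.45. The drug-metabolising monooxygenase gene FMO1 fell by 6.45 (SE 0.39, 87.4-fold lower). The caveolin gene CAV1 (-5.33, 40.2-fold lower) and the IgG receptor gene FCGR1A (-2.96, 7.80-fold lower, SE 0.092) fell too. FCER1A was at least 3.60-fold lower, and its dim second probe did not pass. Of the 8 interferon genes 5 rose, among them CXCL10 by 2.28 and OAS1, an enzyme of the antiviral RNase L pathway, by 1.61, with a list mean of 0.91 (adjusted p = 0.00445, adjusted p = 0.0684 with an estimated correlation). Macrophage and dendritic cell genes fell with a list mean of -0.84, with FCGR1A and the metal transporter gene SLC11A1 (-2.01) past the test of 7 (adjusted p = 0.0305, adjusted p = 0.0602 with an estimated correlation), although a second SLC11A1 probe at -0.63 was under 2-fold, and that call ended with normexp (mean -0.55) and without array 3. The T cell list mean was 0.66 and did not pass (adjusted p = 0.303). With normexp FCER1A was at -0.38, under 2-fold and under its bound, FCGR1A at -1.87 and KRT12 at 1.52, and in the deposited table the interferon mean was 0.46.

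In Dog 7, the chloride channel gene CFTR rose by 4.19 (SE 0.23, 18.3-fold), SCN10A by 4.09, EPB41L5 by 3.19 (1 of 3 sensitive arrays well above background) and the cold-shock protein gene YBX3 by 2.72 (6.59-fold). MX1 fell by 4.59 (SE 0.049, 24.2-fold lower), and the guanylate cyclase gene GUCY1B1 (-3.31), DLA-DOB (-3.23, 9.37-fold lower) and the gelatinase gene MMP9 (-3.08, 8.48-fold lower) fell too. Of the 8 interferon genes 6 fell, OAS2 (-2.88) among them, with a list mean of -1.87 (adjusted p = 3.6e-05, adjusted p = 0.0154 with an estimated correlation). Of the 7 MHC class II genes 6 fell, DLA-DMA (-1.64) among them, with a list mean of -1.53 (adjusted p = 2e-06, adjusted p = 0.000939 with an estimated correlation). MHC class I genes had a list mean of -0.51, with DLA-79 (-1.22) and TAPBP (-1.03) past the test (adjusted p = 0.0248, adjusted p = 0.195 with an estimated correlation). In the NF-kB list the costimulatory gene CD86 fell by 2.18 and IL6 was at least 1.84-fold lower, 2 of 12 members, with a list mean of -0.72 (adjusted p = 0.000407, adjusted p = 0.00448 with an estimated correlation). Stroma and endothelium genes fell as well, 7 of 11, among them CXCL12 (-2.34) and CCL19 (-2.29), with a list mean of -1.34 (adjusted p = 7.5e-05, adjusted p = 0.00448 with an estimated correlation), and the T cell list mean was -1.02 (adjusted p = 0.183). IL6 did not pass under normexp (log2 change -0.15), in the scaled table or on its other probe (-0.38), 2 dim MMP9 probes did not pass, and the second TAPBP probe at -0.67 was under 2-fold. TAPBP was also just under 2-fold with normexp, in the scaled table, without array 3, without the 3 arrays rich in outlier spots and with slide as a block (-0.97). In the deposited table CFTR was at 2.76 and EPB41L5 at 1.27, and SCN10A was at 2.39.

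In Dog 8, MX1 fell by 9.21 (SE 0.049, 594-fold lower). OAS1 (-5.32, 40.0-fold lower) and EIF2AK2, the double-stranded RNA sensor kinase PKR (-4.75, with 1 of 3 resistant arrays well above background), fell too. The lymphocyte antigen gene CD52 was at least 8.45-fold lower. SCN10A rose by 4.59 (SE 0.29), CCR3 by 3.72 (13.2-fold), the prostaglandin receptor gene PTGER2 8.57-fold (1 of 3 sensitive arrays well above background), and the cytokine gene IL21 was at least 3.35-fold higher. Of the 8 interferon genes 6 fell, with a list mean of -3.50 (adjusted p = 1.1e-11, adjusted p = 0.000939 with an estimated correlation). DNA repair genes rose with a list mean of 0.59, 1 of 5 members at least 2-fold, and BRCA1 at 0.81 (adjusted p = 0.000407, adjusted p = 0.0124 with an estimated correlation). IL21 was at 0.90 on its second probe and at 0.97 with normexp, both under 2-fold. Also with normexp, CD52 was at -1.70, under its bound, EIF2AK2 at -2.54 and PTGER2 at 1.17.

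Further lists fell in Dog 8. The NF-kB list fell by 0.89 on average with 5 of 12 members, among them CXCL8 (-2.61) and CCL3 (-1.84) (adjusted p = 0.000124, adjusted p = 0.00277 with an estimated correlation). The MHC class I list fell by 0.75, 1 of 6, TAPBP (-1.13), with DLA88 at -0.89 (adjusted p = 2.5e-05, adjusted p = 0.0198 with an estimated correlation). The MHC class II list mean was -0.22 with 0 of 7 members at least 2-fold, DLA-DQA1 at -0.38 and DLA-DOB at -0.34 (adjusted p = 0.0258, adjusted p = 0.064 with an estimated correlation). Genes of other cell types fell beside these. Stroma and endothelium genes fell by 1.19 on average, 5 of 11, with CCL19 at -4.11 (17.3-fold lower) and CCL21 at least 4.45-fold lower (adjusted p = 0.000144, adjusted p = 0.00454 with an estimated correlation). Macrophage and dendritic cell genes fell by 0.82, 3 of 7, with FCGR1A at -2.57 and FLT3 at least 3.06-fold lower (adjusted p = 0.012, adjusted p = 0.0262 with an estimated correlation). Neutrophil genes fell by 1.14, 3 of 6, with MMP9 at -3.23 and the oxidase gene CYBB at -1.55 (adjusted p = 0.0342, adjusted p = 0.0684 with an estimated correlation), a call that ended at adjusted p = 0.11 with slide as a block. The T cell list mean was -1.09 (adjusted p = 0.32). CXCL8 lay at -3.83, -5.18 and -7.19 on its other 3 probes, MMP9 at 0.34 and 0.23 on 2 dim ones, and TAPBP at -0.80 on its second probe, under 2-fold. With normexp CCL21 was at -0.99 and FLT3 at -0.72, both under 2-fold and under their bounds, and FCGR1A at -1.69, CCL3 was at -1.03 in the deposited table, and with normexp the list means were -0.48 for macrophage and -0.72 for stroma genes. The macrophage call ended with the filter on all arrays, the neutrophil call also without array 1 or 3, and the MHC class II call with normexp, in the deposited table and without array 3.

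In Dog 9, DCN, the gene of the matrix proteoglycan decorin, rose by 3.88 (SE 0.16, 14.7-fold) with 1 of 3 sensitive arrays well above background, the tight junction gene CGN by 3.58 (11.9-fold), UACA by 3.14 (8.79-fold), and the cytokine gene CSF2 was at least 2.10-fold higher. The pro-apoptotic gene BAX fell by 2.35 (SE 0.052, 5.08-fold lower) and the lymphotoxin gene LTB fell 3.35-fold. GRIN2B was at least 3.88-fold and TFAP2B at least 1.43-fold lower. Stroma and endothelium genes rose with a list mean of 1.05, 5 of 11, CXCL12 by 2.33 (adjusted p = 0.00445, adjusted p = 0.0253 with an estimated correlation). Macrophage and dendritic cell genes rose with a list mean of 0.98, 2 of 7, CD163 by 2.20 and FCGR1A by 1.87 (adjusted p = 0.00445, adjusted p = 0.0154 with an estimated correlation). Neutrophil genes rose with a list mean of 1.09, 3 of 6, the antimicrobial peptide gene CAMP by 2.15 and MMP9 by 1.78 (adjusted p = 0.0342, adjusted p = 0.0684 with an estimated correlation). The T cell list mean was 1.43 with 4 of 5 members at least 2-fold higher, and did not pass (adjusted p = 0.0706). TFAP2B did not pass under normexp (-0.07), nor did CSF2 on a dim second probe (0.48) or MMP9 on 2 dim probes (0.41 and 0.29). The second probes of DCN and CGN gave 1.88 and 1.67. With normexp GRIN2B (-0.57) and CSF2 (0.91) were under 2-fold and under their bounds, DCN was at 1.84 and CXCL12 at 1.53. In the deposited table FCGR1A was at 0.88, under 2-fold, MMP9 was at 1.08, and the means of the stroma, macrophage and neutrophil lists were 0.41, 0.35 and 0.48. The neutrophil call ended with normexp, in the scaled table, without array 1 or 3 and without the 3 arrays rich in outlier spots.

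In Dog 10, CAMP fell by 4.16 (SE 0.31, 17.9-fold lower), the protease inhibitor gene SLPI (-3.96, 15.5-fold lower) and RPE65 (-2.80) fell too, and the blood group gene RHCE was at least 3.42-fold lower. DCN rose by 3.37 (SE 0.16, 10.3-fold), CXCL10 by 1.72 (3.30-fold) and CD163 by 1.46 (2.75-fold), and EGF was at least 1.44-fold higher (adjusted p = 0.0264). Neutrophil genes fell with a list mean of -1.35, 3 of 6, with the elastase gene ELANE at -2.11 and well above background on 1 of 3 resistant arrays (adjusted p = 0.0156, adjusted p = 0.0512 with an estimated correlation). Interferon genes rose with a list mean of 0.41, 1 of 8 at least 2-fold with OAS1 at 0.38 (adjusted p = 0.00371, adjusted p = 0.0684 with an estimated correlation). The MHC class II list fell by 0.29, 0 of 7 at least 2-fold, HLA-DRB1 at -0.71 and DLA-DQB1 at -0.69 (adjusted p = 0.027, adjusted p = 0.064 with an estimated correlation). The stroma and endothelium list fell by 0.20, with 1 member higher and 2 lower, CXCL12 (-1.29) and CCL21 (-1.20) (adjusted p = 0.0248, adjusted p = 0.0646 with an estimated correlation). With slide as a block RPE65 was at -0.86 and HLA-DRB1 at -0.30, while EGF (adjusted p = 0.0729), OAS1 (adjusted p = 0.104) and DLA-DQB1 (adjusted p = 0.975) no longer passed. EGF also did not pass without array 1 or 3, nor DLA-DQB1 without array 1 or 2, nor RPE65 on a dim second probe (-0.05) or OAS1 on another probe (0.30) and in the unscaled table. On other probes HLA-DRB1 was at -0.18 and -0.27, and DLA-DQB1 at -0.29, 0.12 and 0.02.

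With normexp RHCE (-0.61), ELANE (-0.63), CXCL12 (-0.53), CCL21 (-0.95) and EGF (0.47) in Dog 10 were under 2-fold, the first and last also under their bounds, and SLPI was at -2.50. DCN was at 2.24 in the deposited table, and CCL21 was at -0.83 with slide as a block. The mean of the stroma and endothelium list in Dog 10 ran from -0.71 with the filter on all arrays to -0.05 with quantile normalisation, and its call ended in the deposited table (-0.32) and without array 3. The calls of the neutrophil and MHC class II lists ended without array 3 too. In the deposited table the MHC class II mean was -0.53 and the interferon mean 0.17, and with slide as a block the MHC class II mean was -0.19.

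Over the 13 lists and 6 dogs, 25 of 78 pairs were called by camera, 8 higher and 17 lower, and 14 were called with an estimated correlation. With slide as a block 26 were called, and within slides 24. The numbers of members past the test were the same over all genes and adjusted over the list alone in all 78 pairs. The interferon list was called in 5 dogs, up in Dogs 5, 6 and 10 and down in Dogs 7 and 8, and in Dog 9 its mean was 0.05 while camera's direction was down (adjusted p = 0.498). The calls in Dogs 6 and 10 were lost at adjusted p = 0.0684 each with an estimated correlation.

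**Figure D3:**
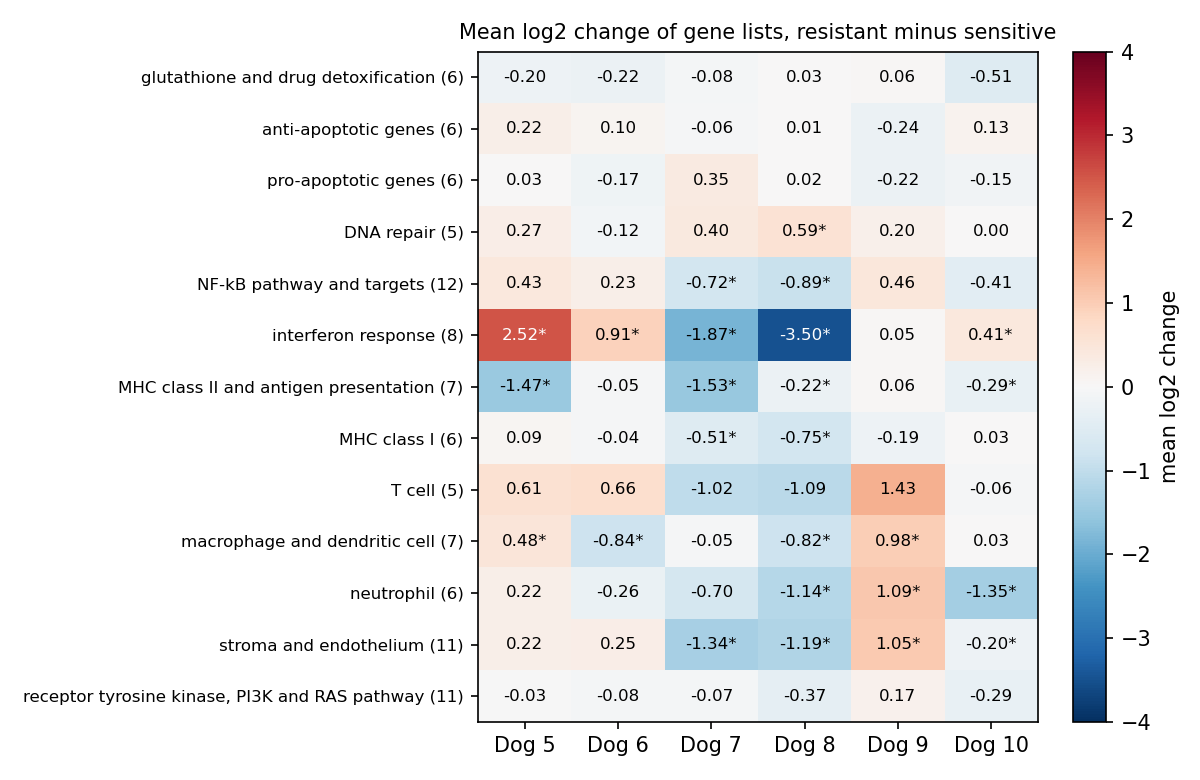
Mean log2 change between phases of the members of each of 13 gene lists in each of the 6 dogs, with the number of measured members in brackets and a star where camera called the list. Interferon response genes run from 2.52 in Dog 5 to -3.50 in Dog 8.

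The third comparison asked whether the changes differed between dogs. They did for 26720 genes (81.2 percent) in limma's F-test of the interaction at an adjusted p under 0.05, and for 24697 genes with slide as a block, a test against array spread only, since each dog and phase is 1 sample. CCR3 (adjusted p = 1.32e-30), ABCB1 (2.68e-26) and GNB3 (4.81e-19) were among them. Of 11248 genes changed in at least 1 dog, 2586 (23 percent) changed in opposite directions in different dogs. CXCL10 was higher in 4 dogs and lower in 2, and IL21 was higher in 4 and lower in 1. MMP9 was higher in 2 dogs and lower in 4, and CAMP higher in 1 and lower in 4. EDN3, the clotting factor gene F8, GNB3 and CCR3 were higher in 4 dogs and lower in 0, and PTGS1, the gene of cyclooxygenase 1, was lower in 4 and higher in 0. These numbers rest on 1 probe per gene. The second GNB3 probe was at least 2-fold higher in Dog 7 alone (1.36), and the second IL21 probe was under 2-fold in Dog 7 (-0.83) and Dog 8 (0.90). In all, 46 genes were higher in exactly 4 dogs against 0.6 expected from independent lists, and 54 were lower in exactly 4 against 2.9. Opposite calls exceeded independent lists as well, in 14 of 15 pairs of dogs (not in Dogs 7 and 10), for example 740 genes against 197.2 in Dogs 8 and 9 and 560 against 147.6 in Dogs 5 and 8.

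Across the 32912 genes, which are not independent replicates, the log2 changes of 2 dogs had a median Pearson correlation of 0.001 over 15 pairs (exact one-sided p = 0.469 over 32 sign patterns of 6 dogs), and -0.05 with slide as a block. Dogs 7 and 8 had the highest correlation, 0.439 (Spearman's rho 0.378), and 0.397 within slides. They shared 1100 lower genes against 150.6 expected and 135 higher genes against 21.9, while 125 genes went opposite ways against 119.2. Dogs 6 and 7 had the lowest correlation, -0.18. Differences between dogs, scan day and slide included, took a median of 65.5 percent of a gene's variance over arrays. Dogs 6 and 7 shared a scan day, as did Dogs 9 and 10, and Dogs 5 and 8 each had their own. Phase changes that differed between dogs took 17.1 percent, arrays 4.33 percent and the phase shared by all dogs 1.92 percent. The 17.1 percent also holds differences between the samples of a dog, because each dog and phase is a single sample. These shares are raw sums of squares, and the shared phase has fewer degrees of freedom than the differing changes. The 17.1 and 1.92 percent therefore cannot be compared directly.

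**Figure D4:**
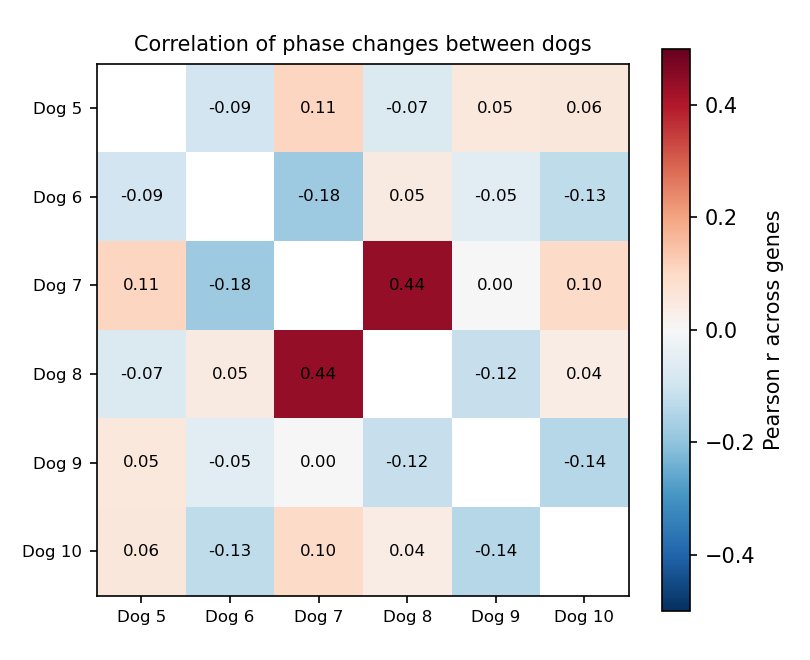
Pearson correlation, across 32912 genes, of the log2 change between phases for each pair of the 6 dogs. The pair of Dogs 7 and 8 stands at 0.439, and all other pairs lie between -0.18 and 0.108.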

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

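The tests of the interferon list on slides, scaling and other cell types, those of Dogs 7 and 8 on slides and dim probes, and all those of ABCB1 were chosen only after the result was seen.

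MS4A1, the gene of the B-cell antigen CD20, stood apart in Dog 5 with a log2 change of -1.06, against -0.26 to 0.14 in the other dogs and a gap to the nearest of 0.671 of the range, beyond Dixon's critical value for 6 dogs. It was the only one of 27 sets of 6 dogs tested that did so. Chance picks out about 1 in 20, so 1 of 27 is no more than chance gives.

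The change between phases differed between dogs for 26720 genes in the test of the interaction. Of 40 joint splits of each dog's 6 arrays, 1 gave as many genes, the real one, and the highest of the others gave 20206. By construction, splits that mix the phases unevenly still carry part of each dog's phase difference. Of 40 joint splits, 1 called as many gene lists within dogs as the real 25, the real one, with 14 in the highest other. These splits cover array spread only, because each dog and phase is 1 sample, so chance differences between the samples of a dog were not excluded for either count.

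Across dogs, all 32 splits of the 6 pairs gave at least as many genes as the real 0, with 0 in the highest other, an outcome that a real count of 0 fixes, so these splits test nothing for genes. For lists chance could not be excluded, since 26 of 32 splits called at least as many as the real 1, with 6 in the highest other. These list calls used the preset correlation of 0.01, while the estimated one reached 0.786 in the interferon list, and whether that or a structure of the samples gave the 6 calls was not tested. Within 1 dog the 10 splits of 6 arrays are too few for a share under 0.05. The real split, which was 1 of these 10, gave 3805 genes in Dog 5 with 73 in the highest other, 1842 with 3 in Dog 6, 3607 with 1 in Dog 7, 2662 with 197 in Dog 8, 3785 with 93 in Dog 9 and 2491 with 1513 in Dog 10.

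Interferon response genes were higher in resistance in Dogs 5 and 6 and lower in Dogs 7 and 8. Slides argue against a slide difference as the cause, since the smallest ratio of the within-slide list mean to the mean over all arrays was 0.993 in these 4 dogs, although each within-slide value rests on 1 array of one phase. Scaling turned none of the 4 means and left each list called at the preset correlation, although the ratio in Dog 6 was 0.506 in the unscaled deposited table, only just above the bound of 0.5 (0.774 was the next lowest), and the Dog 6 call was lost at adjusted p = 0.0684 with an estimated correlation. In Dog 8, 31 T cell, NK cell, macrophage, neutrophil and stroma genes had a median of -0.73 (SD 1.17 over genes), and 14 of them fell at least 2-fold. That median lay 2.23 above the interferon median of -2.95, so interferon genes fell further than the typical gene of these cells. A loss of non-lymphoma cells was not excluded by this, since genes need not fall alike when cells are lost. In Dog 7 the gap between the medians was 0.90 against an SD of 0.94. In neither dog can a loss of such cells and a change within the tumour cells be told apart, and the phase itself stays open, untested.

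The changes of Dogs 7 and 8 were alike, with a correlation of 0.439 across genes. A slide difference was argued against by the design, since Dogs 7 and 8 shared no slide and no scan day. Within the slides that held both phases, with 1 array of one phase in each dog, the correlation was 0.397. Dim probes were argued against by a correlation of 0.486 over 22138 genes well above background on all arrays. The likeness was not limited to genes of the fixed lists, since named genes outside every list had a correlation of 0.508 (566 genes), against 0.614 in the lists (122 genes). A shared change in the resistant tumours or in the cells around them may lie behind it, and neither was tested.

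ABCB1 was higher in resistance in Dogs 5, 6 and 8. A fault of 1 probe was argued against, since the second probe rose by at least 2.42 in these dogs, and a slide difference, since the change within slides, with 1 array of one phase, was at least 2.30. In Dog 8 a gain of T and NK cells, which express ABCB1, was argued against by a median of -0.92 over 7 T cell and cytotoxic genes. Its SE of 0.51 came from resampling these genes and covers no spread between samples. CD8A, CTLA4, ICOS, KLRD1 and CCL5 fell, while CD28 (0.23) and CD4 (0.10) rose slightly, so a gain was not excluded. In Dogs 5 and 6 that median was 1.08 and 0.89, so more T and NK cells and more ABCB1 in the tumour cells cannot be told apart there. For Dog 8, more ABCB1 in the tumour cells is a hypothesis that arose on these same arrays and was not tested.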

How the results depend on the processing

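The normexp correction on the median signal, the table scaled to its 75th percentile, the fit without 3 arrays rich in outlier spots, the values within slides and the sign flips were chosen only after the data were seen. Of the values recomputed, 173 counts and summaries stayed close to the main value and 60 moved, 304 list means stayed on their side of the threshold and 36 lost it, and of the values of named genes by dog 909 stayed, 24 no longer passed and 4 turned sign. Of the values of named genes across dogs 208 stayed and 4 turned. No called list changed sign under any alternative.

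The numbers of changed genes in Dogs 5 to 10 in order were 1955, 984, 1606, 1044, 1452 and 323 with normexp, 2023, 1024, 1723, 1065, 1661 and 344 in the table scaled to its 75th percentile, and 2010, 993, 1950, 1154, 1725 and 760 among genes well above background on all 36 arrays. The first adds an offset, the second keeps the background, and both compress dim signals by construction, while the third tests fewer genes. In the table as deposited there were 1216 in Dog 6, 2005 in Dog 7, 1070 in Dog 8 and 626 in Dog 10. With no minimum fold there were 18740, 16267, 18487, 14566, 19594 and 17318. The median change of all genes by dog ran from -0.208 to 0.234 with normexp, -0.168 to 0.17 in the scaled table and -0.233 to 0.268 in the table as deposited. Dog 10 had 942 with slide as a block, 938 within slides, 790 in a fit of its own 6 arrays, and 1330 to 4166 without array 1, 2 or 3. Across dogs, 631 genes passed with the sample as a random block, a fit that can understate the spread between dogs, and 0 in each other fit. The count changed 2-fold one way in all dogs was 0 to 4 when a dog or an array number was left out, 4 without Dog 10, 2 without Dog 6 and 1 without Dog 9, where fewer dogs are asked of a gene, and 1 without array 2, where the cause was not tested.

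Lists called across dogs numbered 2 with normexp, 2 in the table as deposited, 2 in the scaled table, 2 without a filter, 2 with the filter on all arrays and 2 without the 3 arrays. They numbered 0 with an estimated correlation, 0 in fry, 0 in sign flips and 1 to 5 with a dog or an array number left out, 5 without Dog 5 and 2 without Dog 9, Dog 10 or array 1. The list added to MHC class II was stroma without Dog 9 and MHC class I in each other case with 2, and without Dog 5 these were MHC class I, interferon, NF-kB and stroma. Unlike camera, fry and sign flips test a list against no change. The camera adjusted p of the MHC class II list ran from 3.94e-08 to 0.745 over its alternatives. Within dogs 14 lists were called with an estimated correlation. The share of variance between dogs was 80.4 percent in the table as deposited, 68.4 in the scaled table, 60.9 without a filter, 69.6 with the filter on all arrays, and 59.2 to 69.0 with a dog or an array number left out.

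The list calls of macrophage genes in Dogs 5, 6 and 8, neutrophil genes in Dogs 8, 9 and 10, and stroma genes in Dog 10 ended under at least 1 other scaling, filter or left-out array, as did those of MHC class II genes in Dogs 8 and 10. The mean of BCL2 across dogs was -0.042 in the table as deposited and -0.099 to 0.259 with a dog or an array number left out, below 0 without Dog 6, 8 or 10. DLA-DQB1 in Dog 10 was 0.125 and 0.021 on 2 other probes, and MMP9 in Dog 8 was 0.336 and 0.231 on 2 dim probes. The cause was not tested for these values, unless stated.

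The array numbers 1 to 3 share only a number. Of 18 pairs of same-numbered arrays, 5 had deviations correlated above 0.1, and 17 of 36 arrays were closest to their own number. With the array number as a block the counts in Dogs 5 to 10 were 3799, 1845, 3596, 2662, 3773 and 2479. Without the dog as a block, 0 genes passed across dogs, as with it, and the pairing by dog changed no other call. Within slides 463 genes could not be estimated and were left out. Signal over background limits the dim genes, for which only bounds are given, and it was lowest in Dog 10.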

Other observations

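The relation of the interferon and T cell lists was planned before its result was seen. The genes named in the next paragraph were chosen after their values were seen.

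Several immune and vascular genes had one direction in all 6 dogs without passing the test. CCR1, a receptor for inflammatory chemokines, had a mean log2 change of 0.70 (SE 0.16), the clotting factor gene F8 of 0.99 (SE 0.25) and the integrin gene ITGB3 of 0.44 (SE 0.14), while the endotoxin receptor gene TLR4 lay at -0.62 (SE 0.22) and PDPN, a gene of lymph node stroma, at -0.57 (SE 0.24). Of 688 named genes 23 had one direction, against 21.5 expected with independent signs, so these genes do not stand out by their number. A B cell gene and a vessel gene differed by dog. CD38 lay at 1.14, 0.12, -1.70, -2.00, 0.46 and -0.31 in Dogs 5 to 10 in order, and the adhesion gene VCAM1 at 0.90, 0.73, -2.87, -2.50, 0.02 and 0.09.

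A hypothesis was that interferon genes move with the T cells of a node, which may supply interferon. Over the 6 dogs the mean changes of the interferon and T cell lists had a Pearson correlation of 0.75 (exact permutation p = 0.0917, adjusted p = 0.281 over 5 lists) and a Spearman's rho of 0.6 (exact permutation p = 0.242, adjusted p = 0.743). Without Dogs 8 and 5, the farthest from the median, r was 0.703. For stroma and endothelium genes r was 0.726 (exact permutation p = 0.112, adjusted p = 0.281) with a rho of 0.543 (exact permutation p = 0.297), and 0.733 without Dogs 8 and 5. The r of macrophage genes was 0.451 (exact permutation p = 0.383, rho 0.2), that of neutrophil genes 0.472 (exact permutation p = 0.35, rho 0.371) and that of MHC class II genes -0.144 (exact permutation p = 0.806, rho -0.029), and without Dogs 8 and 5 these moved to -0.218, 0.109 and 0.924, so they rested on those dogs. The bound written beforehand for the T cell list, an adjusted exact permutation p under 0.05, was not met. A missed threshold with 6 dogs excludes nothing, so the relation stays open.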
